A study of Homo sapiens with 33 samples.

How the data were processed

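HT29 cells were profiled by RNA sequencing in 33 libraries: 3 of vehicle and 30 of 4 herbal extracts at 3 doses, 24 h after treatment. The sample labels give 0.1% DMSO for vehicle, while the series text gives another percentage, and which applies was not settled here. Per the labels' protocols, libraries were stranded and read as 100 bp pairs on an MGI sequencer. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned with STAR 2.7.3a to hg38 and quantified with RSEM 1.3.3, and the deposited values are RSEM expected counts per gene. The release of the annotation used for that is not known here. Of the values, 9.45% were not whole numbers, and they were rounded before testing.

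The table holds 273 columns, of which the 33 that map to these samples were used and 240 were not used. Samples were grouped by extract and dose as the labels give them, in 13 groups. The titles put all 33 libraries in batch E. The sample codes begin differently for vehicle, for Sagunja-tang and Samul-tang, and for Palmul-tang and Sibjeondaebo-tang, and the labels do not say what that means. Sagunja-tang and Samul-tang have replicates 2 and 3 only among these samples. Wortmannin, LY294002 and doses based on inhibitory concentrations, which the series text mentions, were not analysed here.

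Of 60675 genes, 17432 passed edgeR's filterByExpr (minimum count 10) and were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, 1 coefficient per group over all 33 libraries, quasi-likelihood F tests, and Benjamini-Hochberg adjustment with a threshold of 0.05. The fit had 20 residual and 7.00 prior degrees of freedom and a common biological coefficient of variation of 0.0489. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic, the error that the test implies. In total 19 comparisons were made: each dose of each extract with vehicle, high with low dose within each extract, and 3 between extracts at the high dose. Positions and biotypes came from GENCODE 29, in which 57055 genes were found by identifier.

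Lists of genes for pathways and cell types, 40 in all with 785 symbols, were written before the data were examined. Of the symbols 679 were measured, and 39 lists had the required 4 measured members; fibroblast markers, with 3 of 12, were not tested. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Member counts are given over all genes and adjusted over the list alone.

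Named genes follow a rule fixed in advance: at the high dose against vehicle the 8 largest rises and 8 largest falls, and elsewhere 4 and 4, among called genes with an average log2 CPM of at least 2, a standard name and every library of one group beyond every library of the other, plus up to 4 members of each list by smallest p. The text names fewer of these, in that order. Some genes of the named results are not reported here.

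The tests were checked on simulated counts with 200 changed genes among 17432. For high-dose Sagunja-tang against vehicle, 31.8, 47.8 and 68.7% of genes changed by log2 0.25, 0.5 and 1 were recovered with 9 false calls (8.33% of calls). For high-dose Palmul-tang these were 47.0, 56.7 and 70.1%, and for Sibjeondaebo-tang against Palmul-tang 33.3, 52.2 and 68.7% with 10 false calls (8.85%), above the nominal 5%. A list shifted in the simulation was called with both correlations, and 0 of 38 unchanged lists were called by camera. The simulated genes varied independently and these lists were drawn at random. The check therefore cannot show how often camera calls unchanged lists of correlated genes at the preset correlation.

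Alternatives were DESeq2 1.42.0, its size factors in edgeR (RLE), no filter on low counts, only the groups compared, replicate number as a block, and leaving out each library in turn. DESeq2 was also run without that filter, so it differs from the main test in the genes entered as well as in method. Of the alternatives, removal of GC and length trends, thinning of all libraries to one depth, and a limit on average log2 CPM for the correlations were added after the data were seen. A group left with 1 library was assumed to vary like the others. The filter was applied anew with a library left out or with only the groups compared, so the tested genes could change. With 1 library left in a group, the filter asked for fewer libraries and could let in more genes of low counts.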

Results

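RNA was sequenced from HT29 cells, a human colorectal adenocarcinoma line, after 24 h with 70% ethanol extracts of 4 herbal formulas or with vehicle (0.1% DMSO in the sample labels). Sagunja-tang and Samul-tang are separate formulas, Palmul-tang combines the herbs of both, and Sibjeondaebo-tang adds further herbs to those of Palmul-tang. Each extract was given at 500, 100 and 20 µg/mL, called high, medium and low below. There were 3 vehicle libraries, 2 libraries per dose of Sagunja-tang and Samul-tang, and 3 per dose of Palmul-tang and Sibjeondaebo-tang, 33 in all. Total counts, in units of 1e6, ran from 31.1 to 35.6 in vehicle and from 28.6 to 49.1 with extracts. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The titles put all 33 libraries in batch E, and the sample codes of vehicle begin differently from those of extracts, for which the labels give no meaning. Fold changes are log2 values ± SE, CPM are means ± SD, and gene positions are on hg38.

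With high-dose Sagunja-tang (n = 2) against vehicle (n = 3), genes of the NRF2 oxidative stress response rose, and MUC17 and MUC12 were among the genes that fell. AKR1B10, an aldo-keto reductase gene (ENSG00000198074, chromosome 7, 134527592 to 134541408), rose by 0.94 ± 0.06 from 98.5 ± 6.31 to 189 ± 16.4 CPM. NQO1, the quinone reductase gene (ENSG00000181019, chromosome 16, 69706996 to 69726951), rose by 0.63 ± 0.05 from 470 ± 29.2 to 727 ± 78.9 CPM. AKR1C3 went from 38.4 ± 4.66 to 97.2 ± 26.6 CPM (1.33 ± 0.14), although the AKR1C genes are near-identical neighbours on chromosome 10 and reads may be shared among them. ZACN (2.66 ± 0.55), TMEM160 (1.47 ± 0.23) and S100A2 (1.19 ± 0.19) were among the largest rises. The membrane mucin genes MUC17 (-1.26 ± 0.22) and MUC12 (-1.02 ± 0.17) and the proline transporter gene SLC6A20 (-1.06 ± 0.08) were among the largest falls. The 2 replicates of this group differed along gene length, with longer genes lower in replicate 2 (Spearman -0.519). Part of these rises and falls may therefore follow gene length.

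Of the 25 measured NRF2 targets, 18 rose and 1 fell with high-dose Sagunja-tang, the same numbers when adjusted over the list alone, and the list was higher than other genes by camera (median 0.29, adjusted p = 2.94e-10). That call was lost with adjusted p = 0.0691 with an estimated correlation. DNA replication and E2F targets rose in 21 of 30 members (22 higher and 1 lower adjusted over the list alone), with GINS1 at 0.46 ± 0.05 and MCM3 at 0.34 ± 0.04, and this list held (adjusted p = 0.0261 with an estimated correlation). Markers of goblet and secretory cells fell in 10 of 18 members and rose in 2, also adjusted over the list alone, led by MUC13 at -0.72 ± 0.04 and REG4 at -0.79 ± 0.08 (adjusted p = 0.125 with an estimated correlation). The lists were not tested with GC and length trends removed. In total edgeR's quasi-likelihood test called 3257 genes higher and 3134 lower, and 3230 and 2957 with GC and length trends removed. Without replicate 2 of this group, which differed from replicate 3 more than any other pair of replicates differed, 2884 genes were called, and with only the groups compared 2182.

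High-dose Samul-tang (n = 2) raised NRF2 targets, led by aldo-keto reductases. AKR1B10 rose 3.44-fold (1.78 ± 0.05) to 339 ± 5.57 CPM and AKR1C2 rose by 2.13 ± 0.08 from 11.6 ± 1.00 to 50.7 ± 1.12 CPM. SLC38A4, which encodes an amino acid transporter (ENSG00000139209, chromosome 12, 46764761 to 46832408), rose 5.04-fold from 2.90 ± 0.434 to 14.5 ± 0.395 CPM. ALDH3A1, an aldehyde dehydrogenase gene, rose by 1.36 ± 0.05 and ABCG1, a sterol exporter gene, by 1.23 ± 0.12. CD200 (-1.20 ± 0.11), TP53INP2 (-1.13 ± 0.08), the urea transporter gene SLC14A1 (-1.11 ± 0.15) and SYTL2 (-1.06 ± 0.07) fell.

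NRF2 targets rose in 24 of 25 members with high-dose Samul-tang, also adjusted over the list alone (median 0.65, adjusted p = 1.41e-35, and 0.000146 with an estimated correlation). SLC7A11, the cystine transporter gene, went from 145 ± 10.8 to 283 ± 0.182 CPM. Targets of PPAR and genes of fatty acid oxidation rose in 11 of 20 members and fell in 1 (13 and 1 adjusted over the list alone), with FABP1 at 1.64 ± 0.14 (adjusted p = 0.0016 with an estimated correlation). Hypoxia response genes rose in 9 of 19 members (12 adjusted over the list alone), with NDRG1 at 0.54 ± 0.10 (adjusted p = 0.00887 with an estimated correlation). Glycolysis genes rose in 15 of 20 (16 adjusted over the list alone), with LDHA at 0.27 ± 0.03 (adjusted p = 0.0408 with an estimated correlation). Goblet and secretory markers fell in 7 of 18 and rose in 2 (8 and 2 adjusted over the list alone), with MUC13 at -0.82 ± 0.04 and REG4 at -0.99 ± 0.08 (adjusted p = 0.0331 with an estimated correlation). Cholesterol synthesis genes fell in 13 of 25 and rose in 1 (14 and 1 adjusted over the list alone), INSIG1 by -0.57 ± 0.05, a call lost with adjusted p = 0.163 with an estimated correlation. In total 2620 genes were higher and 2179 lower, and 2285 were called without replicate 2 of this group.

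High-dose Palmul-tang (n = 3) raised NRF2 targets and the sterol exporter gene ABCG1 and lowered SLC14A1 and CD200. SLC38A4 rose by 1.78 ± 0.12 to 9.93 ± 0.834 CPM, AKR1C2 by 1.68 ± 0.07 to 36.9 ± 0.78 CPM, AKR1B10 by 1.48 ± 0.05 to 274 ± 11.9 CPM and ABCG1 (chromosome 21, 42199689 to 42297244) by 1.41 ± 0.11 from 3.17 ± 0.434 to 8.39 ± 1.09 CPM. HMOX1, the heme oxygenase gene, rose by 1.03 ± 0.06 to 22.9 ± 0.491 CPM. SLC14A1 (chromosome 18, 45687025 to 45752520) fell by 1.52 ± 0.14 from 6.38 ± 0.0728 to 2.22 ± 0.0337 CPM, followed by CD200 (-1.22 ± 0.09), TP53INP2 (-1.18 ± 0.07), SYTL2 (-1.09 ± 0.07) and TLE4 (-0.98 ± 0.09).

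With high-dose Palmul-tang, NRF2 targets rose in 24 of 25 members, also adjusted over the list alone (median 0.60, adjusted p = 3.38e-31, and 0.000352 with an estimated correlation). LXR targets rose in 6 of 10, also adjusted over the list alone (adjusted p = 0.0148 with an estimated correlation). PPAR targets rose in 11 of 20 and fell in 1 (12 and 1 adjusted over the list alone), with CPT1A at 0.50 ± 0.04 (adjusted p = 0.00302 with an estimated correlation). Heat shock genes rose in 14 of 17 and fell in 1, also adjusted over the list alone, with FKBP4 at 0.37 ± 0.04 (adjusted p = 0.043 with an estimated correlation). Goblet and secretory markers fell in 8 of 18 and rose in 2, also adjusted over the list alone, with MUC13 at -0.75 ± 0.04 and MUC2 at -0.80 ± 0.12 (adjusted p = 0.0214 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 25 (17 lower and 1 higher adjusted over the list alone), INSIG1 by -0.63 ± 0.04 and HMGCS1 by -0.54 ± 0.06, a call lost with adjusted p = 0.109 with an estimated correlation. In total 3018 genes were higher and 2579 lower.

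With high-dose Sibjeondaebo-tang (n = 3), 3581 genes were higher and 3323 lower, with aldo-keto reductases again among the largest rises. AKR1C2 (chromosome 10, 4987400 to 5018031) rose by 2.07 ± 0.07 to 48.5 ± 1.86 CPM, AKR1B10 by 1.57 ± 0.05 to 292 ± 7.77 CPM and NQO1 by 0.91 ± 0.05 to 880 ± 3.84 CPM. SLC38A4 (1.69 ± 0.13) and ALDH3A1 (1.31 ± 0.05) rose as well. SLC14A1 (-1.46 ± 0.14) and SYTL2 (-1.17 ± 0.07) fell, as did NPIPB4 (-1.10 ± 0.10), which belongs to a family of near-identical copies and is uncertain for that reason.

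All 25 NRF2 targets rose with high-dose Sibjeondaebo-tang, also adjusted over the list alone (median 0.59, adjusted p = 1.95e-28, and 0.00064 with an estimated correlation). PPAR targets rose in 17 of 20 and fell in 1, and the unfolded protein response list rose in 14 of 21 and fell in 2, both also adjusted over the list alone (adjusted p = 0.00153 and 0.0389 with an estimated correlation), with HSPA5, the endoplasmic reticulum chaperone gene, at 0.37 ± 0.04. ATF4 targets rose in 16 of 25, also adjusted over the list alone, with the serine synthesis gene PSAT1 at 0.53 ± 0.05 (adjusted p = 0.0302 with an estimated correlation). Mitosis genes rose in 16 of 30 and fell in 1, also adjusted over the list alone, with CDK1 at 0.48 ± 0.05 (adjusted p = 0.0471 with an estimated correlation). MUC13 (-0.66 ± 0.04) and REG4 (-0.82 ± 0.07) led the goblet and secretory list, in which 8 of 18 fell and 2 rose (9 and 2 adjusted over the list alone), with adjusted p = 0.0907 with an estimated correlation. FOXO targets restrained by PI3K fell in 10 of 18 and rose in 2 (11 and 2 adjusted over the list alone), a call lost with adjusted p = 0.156 with an estimated correlation.

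At the medium and low doses against vehicle, the NRF2 list faded while lists of mitochondrial and ribosomal genes were still called by camera at the preset correlation, though not with an estimated correlation (adjusted p = 0.132 or more over all doses). With an estimated correlation 1 of 39 lists, not named here, was called at these doses, higher with medium-dose Samul-tang. At the medium dose 12 NRF2 targets rose with Samul-tang and 12 with Sibjeondaebo-tang (14 and 13 adjusted over the list alone), and 9 with Palmul-tang (13 adjusted over the list alone), with 1 lower in each. The camera calls of these 3 were lost with adjusted p = 0.205, 0.316 and 0.263 with an estimated correlation, and medium-dose Sagunja-tang gave no call (2 higher, 4 lower, adjusted p = 0.807). At the low dose no extract gave a call for this list (camera adjusted p from 0.172 to 0.874).

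The 13 mitochondrially encoded genes were lower in all 12 comparisons with vehicle, with medians from -0.82 at high-dose Sagunja-tang, where all 13 fell, to -0.41 at low-dose Sibjeondaebo-tang, where 6 fell (11 adjusted over the list alone). These genes took 9.995 ± 1.36% of counts in vehicle and 7.38 ± 0.742% with extracts. The 12 comparisons share the same 3 vehicle libraries, so here and for the lists below they are not 12 separate results. From the low to the high dose, without vehicle, the mitochondrial medians were -0.072, -0.075, -0.016 and -0.060 with Sagunja-tang, Samul-tang, Palmul-tang and Sibjeondaebo-tang. Nuclear-encoded oxidative phosphorylation genes were higher in all 12, in 24 of 27 members at high-dose Sibjeondaebo-tang and 16 at low-dose Samul-tang (26 and 19 adjusted over the list alone). Cytosolic ribosomal protein genes were higher in all 12 as well, in 25 of 30 members at high-dose Sibjeondaebo-tang, also adjusted over the list alone. The ribosomal call was lost for high-dose Samul-tang without vehicle replicate 3 (adjusted p = 0.135) or its own replicate 3 (0.183), and for medium-dose Sagunja-tang without vehicle replicate 3 (0.198) or its own replicate 3 (0.496). All of these calls were lost, with adjusted p = 0.132 or more with an estimated correlation. From the low to the high dose, the medians of nuclear-encoded oxidative phosphorylation genes were 0.159, -0.003, 0.049 and 0.142 in the order of extracts above. Those of ribosomal protein genes were 0.145, -0.038, 0.030 and 0.131. Wnt and beta-catenin targets were lower in all 12, in 7 to 11 of 19 members, led at the high doses by PROX1, a transcription factor gene (-0.76 ± 0.08 with Sagunja-tang, -0.70 ± 0.08 with Samul-tang, -0.92 ± 0.07 with Palmul-tang and -0.82 ± 0.07 with Sibjeondaebo-tang), and adjusted p = 0.0635 was the smallest with an estimated correlation. From the low to the high dose, the Wnt medians were -0.042, -0.002, 0.005 and 0.021 in the same order. 

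**Figure D1:**
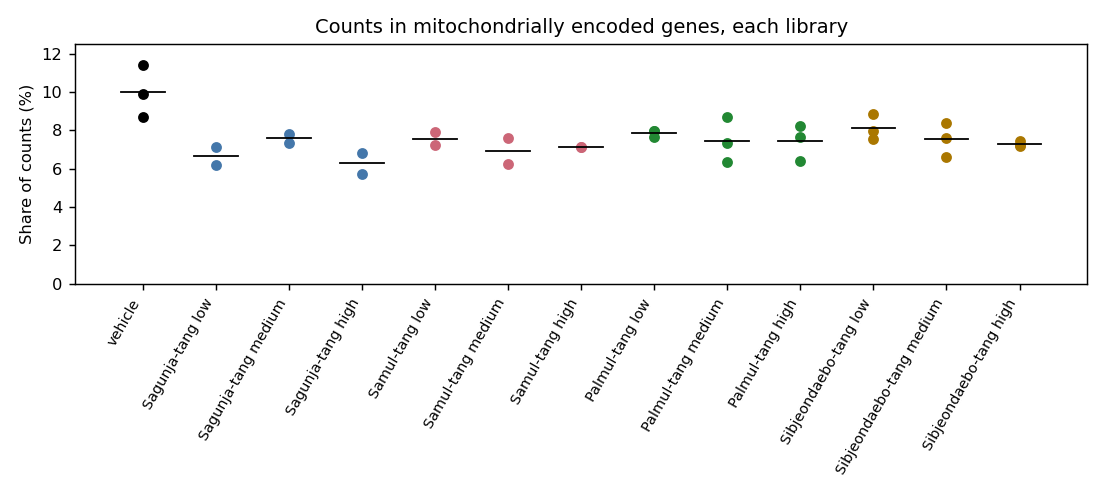
Share of each library's counts in mitochondrially encoded genes, in percent, with 1 point per library, a bar at each group mean and groups along the horizontal axis. The 3 vehicle libraries lie between 8.69 and 11.4% and the extract libraries between 5.71 and 8.83%.

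Medium-dose Sagunja-tang, Samul-tang, Palmul-tang and Sibjeondaebo-tang gave 1464, 1896, 1804 and 2447 genes higher and 1403, 1616, 1679 and 2091 lower. The low doses gave 1942, 1549, 1849 and 1937 higher and 1870, 1518, 1698 and 1902 lower, in the same order. With only the groups compared 1597 genes were called for medium-dose Sagunja-tang and 1779 for medium-dose Palmul-tang. Leaving out single libraries moved these counts. For medium-dose Sagunja-tang 1847 genes were called without vehicle replicate 2, 1549 without vehicle replicate 3, 429 without its own replicate 2 and 1723 without its own replicate 3. For low-dose Sagunja-tang the counts were 2433, 1064 and 2318 without vehicle replicate 3 and its own replicates 2 and 3. For medium-dose Samul-tang 2158 and 633 were called without vehicle replicate 3 and its own replicate 2, and for the low dose 1751, 776 and 996 without vehicle replicate 3 and its own replicates 2 and 3. For medium-dose Palmul-tang 1821, 2168 and 1591 were called without vehicle replicate 3 and its own replicates 1 and 2, and for the low dose 1951 and 1663 without vehicle replicate 3 and its own replicate 2. For Sibjeondaebo-tang the counts without vehicle replicate 3 and without its own replicate 3 were 2988 and 2886 at the medium dose and 2286 and 2177 at the low dose.

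**Figure D2:**
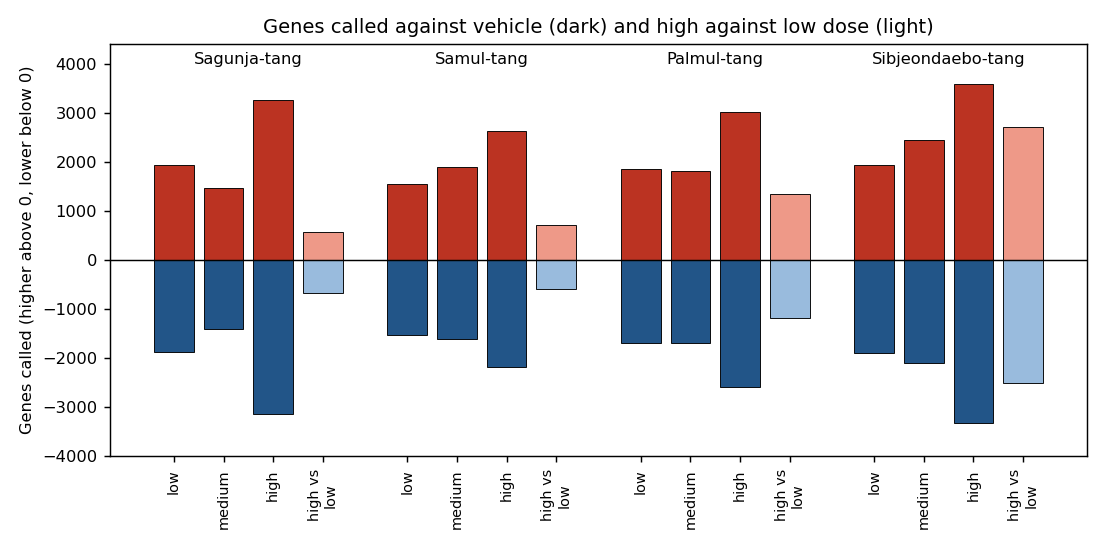
Number of genes called higher (above 0) and lower (below 0) for each extract, against vehicle at each dose in dark bars and for the high against the low dose in light bars. High-dose Sibjeondaebo-tang has 3581 higher and 3323 lower, and the low doses against vehicle have more than the high against the low dose in every extract but Sibjeondaebo-tang.

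The high dose was next compared with the low dose of the same extract, which asks for the effect of dose without the vehicle libraries. NRF2 targets rose in each extract: in 21 of 25 members with Sagunja-tang (median 0.35), 24 with Samul-tang (0.67), 25 with Palmul-tang (0.62) and 24 with Sibjeondaebo-tang (0.75), or 24, 25, 25 and 24 adjusted over the list alone. AKR1C2 rose by 1.08 ± 0.09, 2.23 ± 0.09, 1.64 ± 0.07 and 2.31 ± 0.07 in that order of extracts, and AKR1B10 rose 1.94-, 3.38-, 2.82- and 3.14-fold. GCLM, which encodes a subunit of the enzyme that starts glutathione synthesis (ENSG00000023909, chromosome 1, 93885205 to 93909456), rose by 0.58 ± 0.06 with Sagunja-tang, 0.79 ± 0.05 with Palmul-tang and 0.89 ± 0.05 with Sibjeondaebo-tang. With an estimated correlation the adjusted p values of the list were 0.000503, 9.73e-07, 3.57e-06 and 4.54e-05, so these calls held.

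**Figure D3:**
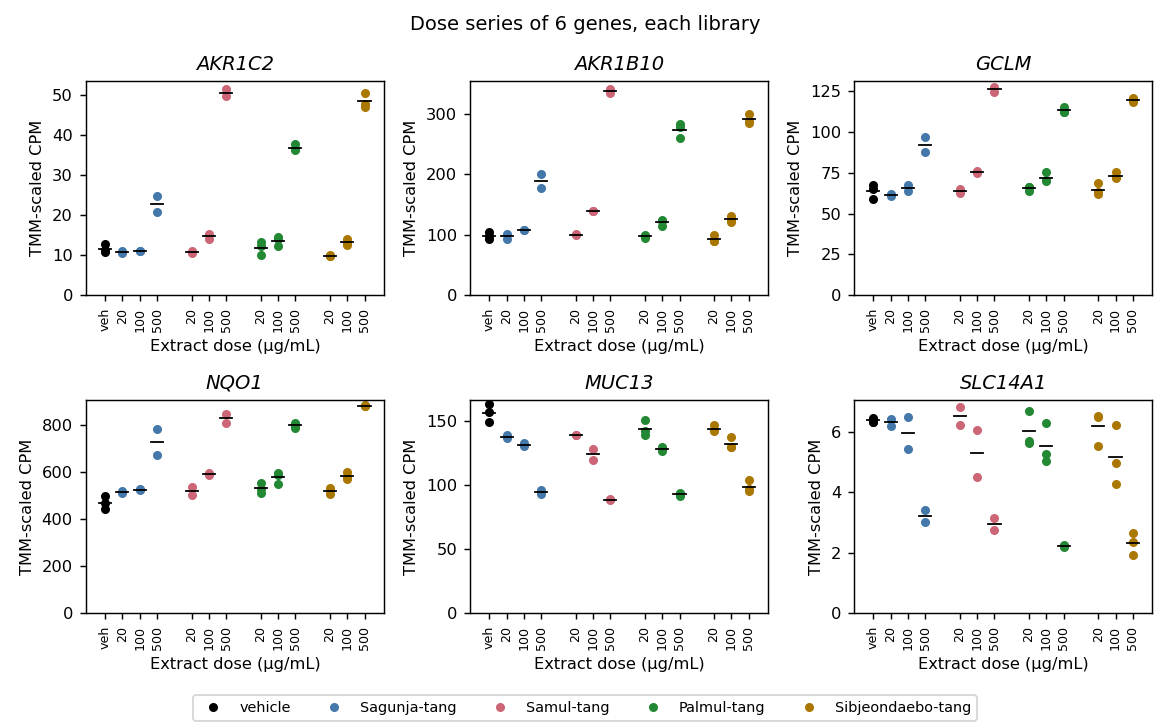
TMM-scaled CPM of 6 genes in each library (points) with group means (bars), for vehicle and for 20, 100 and 500 µg/mL of each extract. AKR1C2, AKR1B10, GCLM and NQO1 are highest and MUC13 and SLC14A1 lowest at 500 µg/mL, as with AKR1C2 at 50.7 ± 1.12 CPM with Samul-tang against 11.6 ± 1.00 in vehicle.

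Genes of protein folding and of ribosome assembly also rose from the low to the high dose. Heat shock genes rose in 6, 11, 13 and 16 of 17 members with Sagunja-tang, Samul-tang, Palmul-tang and Sibjeondaebo-tang (11, 13, 15 and 16 adjusted over the list alone), with the cochaperone gene FKBP4 at 0.26 ± 0.04, 0.37 ± 0.04, 0.35 ± 0.04 and 0.42 ± 0.04. Unfolded protein response genes rose in 9, 10, 9 and 14 of 21 (11, 11, 10 and 14 adjusted over the list alone), with the chaperone gene HSP90B1 at 0.24 ± 0.04, 0.28 ± 0.04, 0.19 ± 0.03 and 0.22 ± 0.03. Ribosome biogenesis and MYC targets rose in 8, 17, 23 and 25 of 26 (11, 26, 26 and 26 adjusted over the list alone). DNA replication genes rose in 13, 7, 14 and 21 of 30 (20, 8, 26 and 22 adjusted over the list alone), with CDC6 at 0.19 ± 0.04, 0.21 ± 0.04, 0.25 ± 0.03 and 0.32 ± 0.03, the first of these lost without low-dose Sagunja-tang replicate 3 (CDC6 adjusted p = 0.0567). Every one of these 16 list calls held with an estimated correlation, with adjusted p = 0.042 at most.

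Among lipid genes, ABCG1 rose by 0.83 ± 0.12 with Samul-tang, 1.04 ± 0.10 with Palmul-tang and 1.02 ± 0.10 with Sibjeondaebo-tang. LXR targets rose in 3, 4, 5 and 5 of 10 members with Sagunja-tang, Samul-tang, Palmul-tang and Sibjeondaebo-tang (4, 4, 5 and 5 adjusted over the list alone, with 1 lower with Sibjeondaebo-tang). The LXR list held with Samul-tang and Palmul-tang (adjusted p = 0.0183 and 0.0138 with an estimated correlation) and was lost with Sagunja-tang and Sibjeondaebo-tang (adjusted p = 0.0564 and 0.0736 with an estimated correlation). The call of the list LXR targets in Sagunja-tang high vs low dose also ended without high-dose replicate 3 (adjusted p = 0.451), and that of the list LXR targets in Sibjeondaebo-tang high vs low dose without low-dose replicate 1 (adjusted p = 0.0517). PPAR targets rose in 3 of 20 with Sagunja-tang (8 higher and 1 lower adjusted over the list alone), with adjusted p = 0.101 with an estimated correlation. Without high-dose replicate 2 the list PPAR targets and fatty acid oxidation in Sagunja-tang high vs low dose had adjusted p = 0.0909. They rose in 7, 9 and 10 of 20 with Samul-tang, Palmul-tang and Sibjeondaebo-tang and fell in 0, 1 and 0 (10, 9 and 10 higher and 1, 2 and 0 lower adjusted over the list alone), and held with adjusted p = 0.00102, 0.00759 and 0.0103 with an estimated correlation. Cholesterol synthesis genes fell in 5, 10, 20 and 13 of 25 with Sagunja-tang, Samul-tang, Palmul-tang and Sibjeondaebo-tang (7, 19, 23 and 16 adjusted over the list alone). LSS, the lanosterol synthase gene (chromosome 21, 46188141 to 46228824), fell by 0.22 ± 0.04, 0.38 ± 0.04, 0.36 ± 0.03 and 0.33 ± 0.03. The cholesterol list held for Samul-tang and Palmul-tang (adjusted p = 0.0284 and 0.0143 with an estimated correlation) and was lost for Sagunja-tang and Sibjeondaebo-tang (adjusted p = 0.445 and 0.208 with an estimated correlation), and for Sagunja-tang also without high-dose replicate 3 (cholesterol synthesis adjusted p = 0.599). Metallothionein and zinc response genes fell with Samul-tang in 3 of 7 members (4 adjusted over the list alone), with MT1E at -0.45 ± 0.10 (adjusted p = 0.0302 with an estimated correlation), and the MT1E call was lost without high-dose Samul-tang replicate 2 (adjusted p = 0.0895) or low-dose replicate 3 (adjusted p = 0.0536).

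Goblet and secretory markers and interferon response genes fell with dose. MUC13 (ENSG00000173702, chromosome 3, 124905442 to 124953819) fell by 0.54 ± 0.05, 0.65 ± 0.05, 0.63 ± 0.04 and 0.54 ± 0.04 with Sagunja-tang, Samul-tang, Palmul-tang and Sibjeondaebo-tang. Its list fell in 6, 7, 10 and 7 of 18 members and rose in 0, 0, 1 and 2 (8, 8, 10 and 9 lower adjusted over the list alone), and held except with Sibjeondaebo-tang (adjusted p = 0.137 with an estimated correlation), where it was also lost without high-dose replicate 2 (goblet and secretory cells adjusted p = 0.0583). Interferon response genes fell in 8, 12, 9 and 15 of 28 (16, 18, 11 and 16 adjusted over the list alone), with STAT2 at -0.26 ± 0.06 with Samul-tang and -0.41 ± 0.05 with Sibjeondaebo-tang, and held with Samul-tang only (adjusted p = 0.0168 with an estimated correlation, against 0.101, 0.0763 and 0.137 with Sagunja-tang, Palmul-tang and Sibjeondaebo-tang). SLC14A1 fell by 0.96 ± 0.16, 1.14 ± 0.16, 1.43 ± 0.14 and 1.42 ± 0.14.

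**Figure D4:**
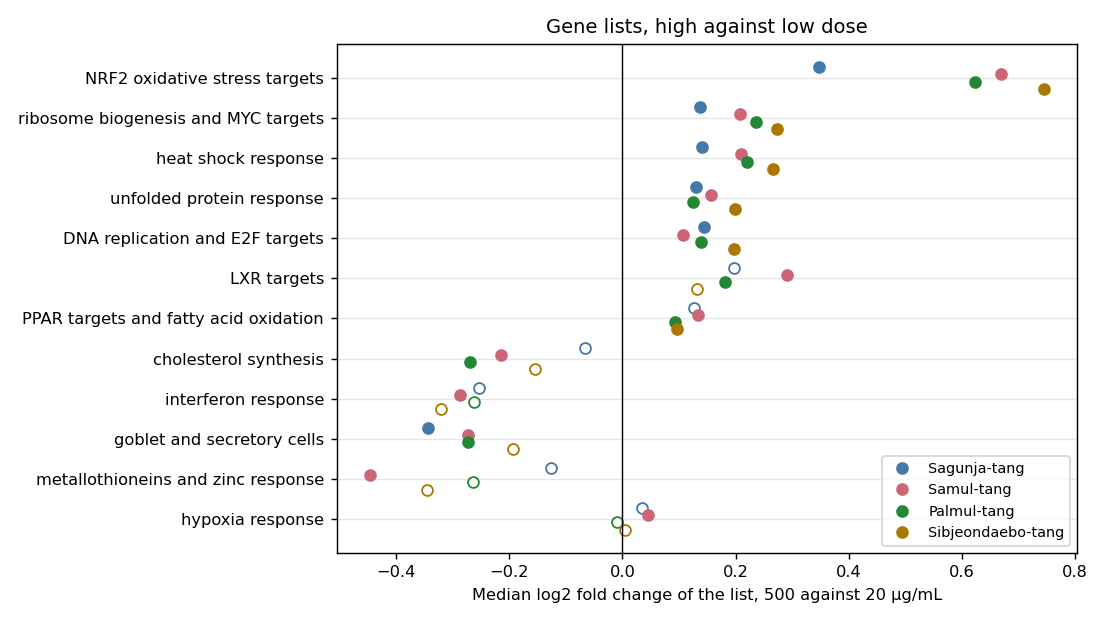
Median log2 fold change of 12 gene lists for 500 against 20 µg/mL, with 1 point per extract, filled where the adjusted p was under 0.05 with an estimated correlation and open otherwise. NRF2 targets lie farthest to the right, at 0.35 to 0.75.

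From the low to the high dose, edgeR called 581 genes higher and 673 lower with Sagunja-tang, 715 and 598 with Samul-tang, 1336 and 1177 with Palmul-tang, and 2707 and 2500 with Sibjeondaebo-tang. The counts of the extracts with 2 libraries per dose moved with single libraries, and that of Sagunja-tang also with the groups that entered the fit. With only the 4 Sagunja-tang libraries of these doses compared, edgeR called no gene, while over all libraries DESeq2 called 1529 and edgeR gave 4139 at an unadjusted p under 0.05. Leaving out 1 library from the fit gave 140 (without high-dose replicate 2), 320 (low-dose replicate 2), 317 (low-dose replicate 3) or 4222 genes (high-dose replicate 3). For Samul-tang 1589 genes were called with only its own libraries compared, and leaving out 1 library gave 584, 547, 682 and 552 genes without high-dose replicate 2, low-dose replicate 2, high-dose replicate 3 and low-dose replicate 3.

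At the high dose, Samul-tang was compared with Sagunja-tang (n = 2 each), the formulas combined in Palmul-tang, and NRF2 targets were higher with Samul-tang. SLC38A4 was higher by 1.55 ± 0.14, at 14.5 ± 0.395 against 4.97 ± 0.0974 CPM. AKR1C2 was higher by 1.16 ± 0.08, at 50.7 ± 1.12 against 22.8 ± 2.71 CPM. AKR1B10 (0.84 ± 0.06), SLC7A11 (0.68 ± 0.05) and GCLC (0.65 ± 0.06) were higher too, and RARRES1 was lower (-0.60 ± 0.08). NRF2 targets were higher in 18 of 25 members (21 adjusted over the list alone, median 0.41), and the list held (adjusted p = 0.000351 with an estimated correlation). The hypoxia response was higher in 6 of 19 members and lower in 1 (8 and 1 adjusted over the list alone), led by NDRG1 at 0.76 ± 0.11, and also held (adjusted p = 0.00899 with an estimated correlation), but the list hypoxia response in Samul-tang vs Sagunja-tang at high dose was lost without Sagunja-tang replicate 3 (adjusted p = 0.0886). Ribosomal protein genes were lower in 2 of 30 members (23 adjusted over the list alone, median -0.21), with adjusted p = 0.334 with an estimated correlation. The median of the list cytosolic ribosomal proteins in Samul-tang vs Sagunja-tang at high dose was -0.07 without Sagunja-tang replicate 2 and -0.33 without Sagunja-tang replicate 3.

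In total 618 genes were higher and 335 lower with Samul-tang than with Sagunja-tang. Leaving out 1 library gave 64 genes (without Sagunja-tang replicate 2), 105 (Samul-tang replicate 2), 147 (Samul-tang replicate 3) or 4092 (Sagunja-tang replicate 3), and a fit of these 4 libraries alone called 2, SLC38A4 and AKR1C2. The count was 463 with GC and length trends removed (261 of them higher), 1746 without the filter (949 and 797) and 1473 with the replicate block.

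Sibjeondaebo-tang was compared with Palmul-tang at the high dose (n = 3 each), and 613 genes were lower and 61 higher. At equal mass of extract, Sibjeondaebo-tang need not hold the full dose of the Palmul-tang herbs. The added herbs and a smaller amount of the shared ones therefore cannot be told apart. The golgin gene GOLGA8B (chromosome 15, 34525207 to 34588503) was lower by -1.04 ± 0.09, at 17.8 ± 1.96 against 36.7 ± 0.562 CPM, although it has near-identical copies and is uncertain. The kinesin gene KIFC2 (chromosome 8, 144466043 to 144474202) was at 5.53 ± 1.16 against 10.5 ± 0.671 CPM (-0.93 ± 0.12), and the noncoding LINC00342 was lower by the same log2 value, -0.93 ± 0.12. AKR1C2 (0.39 ± 0.06) and the chloride channel gene CLIC3 (0.35 ± 0.07) were higher. The number of higher genes moved with the setting: it was 184 with DESeq2, 157 without the filter, 121 with only the groups compared, 120 with the replicate block and 120 with trends removed. Of the NRF2 targets, 2 were higher and 1 lower (8 and 1 adjusted over the list alone), ABCC3 at -0.23 ± 0.04. Camera called 6 lists higher, among them NRF2, cholesterol synthesis, glycolysis and lysosome and autophagy genes, and none held (adjusted p = 0.388, 0.388, 0.386 and 0.311 with an estimated correlation). Cholesterol synthesis had 0 members called (6 higher adjusted over the list alone), glycolysis had 2 higher (3 higher and 1 lower adjusted over the list alone) and the lysosome list had 1 higher and 1 lower (2 and 1 adjusted over the list alone). Without Palmul-tang replicate 3, 435 genes were called.

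Palmul-tang was compared at the high dose with the mean of Sagunja-tang and Samul-tang, since it combines their herbs, and 6 genes differed. The sample codes of Palmul-tang begin differently from those of the other formulas here. What the codes mark is not known, so a difference in handling cannot be told apart from one of the extracts. The hypoxia-induced gene NDRG1 (chromosome 8, 133237171 to 133302022) was lower by -0.53 ± 0.09 (adjusted p = 0.0153) and the glycolytic aldolase gene ALDOC by -0.30 ± 0.05, and the actin-binding protein gene COTL1 was higher (0.20 ± 0.04). These calls ended when 1 library was left out: NDRG1 had adjusted p = 0.107 without Samul-tang replicate 2, 0.188 without Palmul-tang replicate 1 and 0.0592 without Palmul-tang replicate 2. Without Sagunja-tang replicate 2, Samul-tang replicates 2 and 3 and Palmul-tang replicates 1, 2 and 3 in turn, ALDOC had 0.0813, 0.107, 0.0785, 0.188, 0.185 and 0.136 and COTL1 0.0642, 0.156, 0.0706, 0.188, 0.142 and 0.173. The hypoxia response was lower with 1 of 19 members called (8 adjusted over the list alone, median -0.12). Ribosome biogenesis and MYC targets were higher with none of 26 called (9 adjusted over the list alone, median 0.08). Both held with adjusted p = 0.000505 and 0.000648 with an estimated correlation. NRF2 targets had a median of 0.09 with none called (8 adjusted over the list alone), and adjusted p = 0.065 with an estimated correlation. At an unadjusted p under 0.05, 1942 genes differed. DESeq2, run without the filter, called 71, edgeR without the filter 370, with trends removed 3 and with only the groups compared 0. The count was 0 without Samul-tang replicate 2, Palmul-tang replicate 1 or Palmul-tang replicate 2, 1 without Sagunja-tang replicate 2, 2 without Samul-tang replicate 3 and 1116 without Sagunja-tang replicate 3.

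Effects of different extracts were compared gene by gene. The high minus low dose effects, which share no libraries, correlated across genes at 0.780 between Samul-tang and Palmul-tang, 0.740 between Palmul-tang and Sibjeondaebo-tang, 0.667 between Samul-tang and Sibjeondaebo-tang, 0.622 between Sagunja-tang and Palmul-tang, 0.595 between Sagunja-tang and Sibjeondaebo-tang and 0.475 between Sagunja-tang and Samul-tang. These values are over genes with an average log2 CPM of at least 2, a limit set after the data were seen. Over all 17432 tested genes the correlations were 0.313, 0.284, 0.227, 0.175, 0.166 and 0.065 in the same order, and genes are not independent replicates. Without the filter the correlations were 0.0386, 0.042, 0.0343, 0.0188, 0.0327 and 0.00373 in the same order. Leaving out 1 library also lowered most of the correlations, here over the genes that then passed the filter. The filter was applied anew, and with 1 library left in a group it could let in more genes of low counts. These values are therefore not over the same 17432 genes, and the drop need not come from the library itself. Samul-tang and Palmul-tang gave 0.163 without low-dose Samul-tang replicate 3, and Samul-tang and Sibjeondaebo-tang 0.109 and 0.133 without low-dose Samul-tang replicates 2 and 3. Sagunja-tang and Palmul-tang gave 0.0914 without high-dose Sagunja-tang replicate 2 and 0.0573 without low-dose Sagunja-tang replicate 3, and Sagunja-tang and Sibjeondaebo-tang 0.101 and 0.0973 without low-dose Sagunja-tang replicates 2 and 3. Sagunja-tang and Samul-tang gave 0.0164, 0.0271 and 0.018 without Sagunja-tang high-dose replicates 2 and 3 and low-dose replicate 3, and 0.00127, 0.04 and 0.0428 without Samul-tang high-dose replicate 2 and low-dose replicates 2 and 3.

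At the high dose against vehicle, Palmul-tang and Sibjeondaebo-tang shared 2535 higher and 2039 lower genes, where independent lists would share 620 and 492, and 30 genes were called in opposite directions. In 20 simulations of unchanged groups against the same vehicle libraries no pair shared a call, a value that the call threshold nearly fixes in advance. Samul-tang and Palmul-tang shared 2142 and 1633 (independent 454 and 322, 1 opposite), Sagunja-tang and Palmul-tang 2291 and 1870 (564 and 464, 5 opposite), and Sagunja-tang and Samul-tang 1899 and 1570 (489.5 and 392, 15 opposite). Sagunja-tang and Sibjeondaebo-tang shared 2456 and 1933 (669 and 597, 51 opposite), and Samul-tang and Sibjeondaebo-tang 2087 and 1586 (538 and 415, 38 opposite). Fold changes correlated across genes from 0.598 (Sagunja-tang and Samul-tang) to 0.729 (Palmul-tang and Sibjeondaebo-tang), where unchanged groups simulated against the same vehicle libraries gave 0.413 and 0.547, and the covariances were 0.171 and 0.171 against simulated 0.0469 and 0.0481. With 3 vehicle libraries the controls could not be split into parts of at least 2, so part of the excess may come from the shared vehicle libraries. Without high-dose Samul-tang replicate 2 the shared calls of Samul-tang fell to 1782 with Sagunja-tang, 2057 with Palmul-tang and 1907 with Sibjeondaebo-tang, and without high-dose Sagunja-tang replicate 2 those of Sagunja-tang fell to 2590 with Palmul-tang and 2407 with Sibjeondaebo-tang.

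Lists of fatty acid synthesis, apoptosis regulators, NF-kB, epithelial junctions, glucocorticoid, estrogen and YAP targets and of leukocyte, endothelial, and liver and neuroendocrine markers were called in none of the 19 comparisons.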

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

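The tests of depth and of GC content and length for the first 2 patterns below, the count of protein-coding genes, the NRF2 levels of single libraries and the other splits of the samples were chosen only after the result was seen. The dose effect (high minus low) of Samul-tang differed from that of Sagunja-tang in 24 genes, 20 higher and 4 lower, by a test of the difference itself. SLC38A4 (1.28 ± 0.22), AKR1C2 (1.15 ± 0.13) and AKR1B10 (0.80 ± 0.09) rose more with Samul-tang, and the median difference of NRF2 targets was 0.39, which held with an estimated correlation. The dose effect of Sibjeondaebo-tang differed from that of Palmul-tang in 252 genes, 5 higher and 247 lower, with AKR1C2 at 0.67 ± 0.10 and KIFC2 at -0.99 ± 0.16.

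At the low dose, 2077 genes were called the same way against vehicle in all 4 extracts, 1039 higher and 1038 lower, where independent lists would share 2.03 and 1.73. The 4 lists are not independent, since they share the vehicle libraries, so part of the excess may come from these. In 20 simulations of unchanged groups against the same vehicle libraries the 4 lists shared 0 genes, a value that the call threshold nearly fixes in advance. After thinning to one depth 1625 (78.2%) kept the call, which missed the bound of 80%. Thinning also removes reads and so power, so depth stays open. A ratio of median fold changes, put in place of the count after it missed the bound, was dropped again, since thinning leaves it near 1 whatever the cause. With GC and length trends removed, 1848 of 2073 kept the call, which argues against those trends as the whole cause. Vehicle libraries handled apart and a response to the extracts (1158 genes also called at all 4 high doses) cannot be told apart. The same vehicle libraries enter all 4 comparisons. Ratios of high-dose to low-dose median were 1.15, 0.972, 0.931 and 0.872 with Sagunja-tang, Samul-tang, Palmul-tang and Sibjeondaebo-tang. From the low to the high dose, 91, 69, 119 and 277 of these genes were called further from vehicle. In the opposite direction, 78, 140, 313 and 571 were called. The genes were picked by their low-dose calls, which by itself favours smaller values at the high dose. The titles name 1 batch for all libraries. The sample codes of vehicle begin differently from those of extracts, and the labels do not say whether vehicle was handled apart.

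Between Sibjeondaebo-tang and Palmul-tang, 613 of 674 called genes were lower. After thinning 454 (74.1%) kept the call, again under the bound of 80%. Thinning also removes power, so that count cannot decide on depth. At one depth, however, 477 genes were still lower and 56 higher. Total counts before thinning overlapped, from 4.07e+07 to 4.54e+07 with high-dose Sibjeondaebo-tang and from 4.05e+07 to 4.91e+07 with high-dose Palmul-tang. These values argue against depth as the cause of the excess of lower genes. With trends removed 580 of 605 stayed lower. The median of lncRNA genes lay below that of protein-coding genes by a difference of -0.18, so a lower yield of noncoding transcripts may contribute. Yet 429 of the 613 were protein-coding, for which that explanation leaves the fall open. By class, 3.74% of 2887 tested lncRNA genes and 3.23% of 13265 protein-coding genes were called lower. Against vehicle, the same difference of medians was 0.015, -0.084 and -0.233 at the low, medium and high dose of Sibjeondaebo-tang. At high-dose Palmul-tang it was -0.054. An effect of the added herbs, or of less of the Palmul-tang herbs at equal mass of extract, stays open as well.

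Replicates 2 and 3 of high-dose Sagunja-tang differed with an SD of log2 differences of 0.259, against at most 0.175 in 26 other pairs. The SD was 0.258 at one depth and 0.230 with trends removed, so neither depth nor trends with GC content and length, as removed here, account for it, although the difference followed gene length (Spearman -0.519). Of the 12 other group means 3 lay closer to replicate 2 than replicate 3 did, the nearest being high-dose Sibjeondaebo-tang. The mean log2 level of NRF2 targets over vehicle was 0.42 in replicate 2 and 0.31 in replicate 3, against at most 0.17 in vehicle, low-dose and medium-dose libraries and at least 0.67 in the other high-dose libraries, which argues against a swap with one of these groups. A sample from outside them stays open, and no biological explanation was tested.

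For comparisons of 3 with 3 libraries, 10 splits exist, too few for a share under 0.05, and 1 split, the real one, gave as many genes in each. The real count and the highest of the other splits were 5597 and 2, 3483 and 529, and 3547 and 1 for Palmul-tang at the high, medium and low dose. They were 6904 and 0, 4538 and 1, and 3839 and 9 for Sibjeondaebo-tang, 2513 and 0 and 5207 and 0 for high against low dose of Palmul-tang and Sibjeondaebo-tang, and 674 and 0 between these extracts (edgeR).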

How the results depend on the processing

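The alternatives with GC and length trends, one depth and a limit on average log2 CPM were chosen only after the data were seen, and the trend correction was given a second normalization after a first version without it shifted the splits into higher and lower genes. Of 258 list calls, 81 held with an estimated correlation, 239 with fry, 258 without the filter, 247 with the replicate block, 257 with RLE and 230 with only the groups compared. List calls were not tested with trends removed, at one depth or with DESeq2. Of the values for named genes, 2142 of 2176 stayed past the threshold the same way with DESeq2, 2094 of 2200 with trends removed, 2069 at one depth, 2072 without the filter, 2186 with the block, 2190 with RLE, 1788 of 2198 with only the groups compared and 9899 of 11836 with a library left out. RLE and thinning moved no count of calls by over 1.5 times. Replicate numbers were not taken to pair the samples, since not every correlation was over 0.1: those of 177 pairs ran from -0.17 to 0.17 with a median of 0.024, and 16 were over 0.1. A bar that all 177 pairs must pass is strict, so missing it does not show that the samples were unpaired. Of the 33 libraries, 24 correlated best with their own number, a hint that the numbers may carry some shared variation. The block moved Samul-tang against Sagunja-tang from 953 to 1473 genes, so a pairing stays open. The cause was not tested for the changes below. Fewer samples or genes entered where the setting says so. More genes entered without the filter and with DESeq2, and more could enter with a library left out of Sagunja-tang or Samul-tang.

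With only the groups compared, 2182 genes were called for high-dose and 1597 for medium-dose Sagunja-tang, 1779 for medium-dose Palmul-tang, 0 for Sagunja-tang high against low dose, 2 for Samul-tang against Sagunja-tang (2 higher, 0 lower) and 0 for Palmul-tang against the mean, by edgeR. Without the filter Samul-tang against Sagunja-tang gave 1746 (949 higher, 797 lower) and Palmul-tang against the mean 370 (233 and 137). DESeq2 was run without the filter as well, so genes of low counts entered here and in its correlations below. It gave 71 for Palmul-tang against the mean (45 and 26) and 184 higher and 592 lower for Sibjeondaebo-tang against Palmul-tang. With trends removed Samul-tang against Sagunja-tang gave 463 and Palmul-tang against the mean 3 (0 and 3), and at one depth the latter gave 0 higher and 5 lower. Dose effect correlations without the filter and with DESeq2 were 0.00373 and 0.0103 (Sagunja-tang and Samul-tang), 0.0188 and 0.0298 (Sagunja-tang and Palmul-tang), 0.0327 and 0.0453 (Sagunja-tang and Sibjeondaebo-tang), 0.0386 and 0.0528 (Samul-tang and Palmul-tang), 0.0343 and 0.0514 (Samul-tang and Sibjeondaebo-tang) and 0.0420 and 0.0635 (Palmul-tang and Sibjeondaebo-tang). With the limit on average log2 CPM they were 0.475, 0.622, 0.595, 0.780, 0.667 and 0.740 in the same order.

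Directions reversed in 5 values: with trends removed, VEGFA (0.0256, adjusted p = 0.683) and KDM3A (0.00956, adjusted p = 0.907) in high-dose Sagunja-tang; without vehicle replicate 1, CYP1A1 (ENSG00000140465) in Sagunja-tang low dose vs vehicle (0.296, lowest -1.96 without vehicle replicate 2) and CYP1A1 (ENSG00000140465) in Palmul-tang low dose vs vehicle (0.0284, lowest -2.23 without vehicle replicate 2). The last was the median of cytosolic ribosomal proteins in Sagunja-tang high against low dose, -0.00473 without high-dose replicate 2 and at most 0.25 without high-dose replicate 3.

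With each library left out in turn, calls against vehicle ran from 2884 to 6923, 429 to 3095 and 1064 to 3986 for high-, medium- and low-dose Sagunja-tang, 2285 to 4852, 633 to 3731 and 776 to 3290 for Samul-tang, 4267 to 5472, 1591 to 3956 and 1663 to 3680 for Palmul-tang, and 5695 to 6631, 2886 to 4533 and 2177 to 3882 for Sibjeondaebo-tang. High against low dose gave 140 to 4222, 547 to 682, 1725 to 1974 and 4049 to 4532 in that order of extracts. Samul-tang against Sagunja-tang gave 64 to 4092, Sibjeondaebo-tang against Palmul-tang 435 to 547 and Palmul-tang against the mean 0 to 1116. Shared calls ran from 1782 to 3654 (Sagunja-tang and Samul-tang), 2590 to 4275 (Sagunja-tang and Palmul-tang), 2407 to 4613 (Sagunja-tang and Sibjeondaebo-tang), 2057 to 3890 (Samul-tang and Palmul-tang), 1907 to 3811 (Samul-tang and Sibjeondaebo-tang) and 3400 to 4569 (Palmul-tang and Sibjeondaebo-tang). Dose effect correlations ran, in the same order, from 0.00127 to 0.0839, 0.0573 to 0.172, 0.0973 to 0.183, 0.163 to 0.298, 0.109 to 0.277 and 0.225 to 0.293. In all of these fits the filter was applied anew, so the tested genes could change with the library left out.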

Other observations

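The correlation with trends removed and the counts among the 613 genes below were chosen only after the result was seen. From the low to the high dose, SLC7A11, the cystine transporter gene, rose by 1.03 ± 0.05 with Samul-tang and 0.78 ± 0.04 with Palmul-tang. ACSS2, whose product makes acetyl-CoA from acetate, fell by 0.61 ± 0.08, 0.90 ± 0.08, 0.96 ± 0.07 and 1.06 ± 0.07 with Sagunja-tang, Samul-tang, Palmul-tang and Sibjeondaebo-tang. The fatty acid hydroxylase gene CYP4F3 rose by 1.32 ± 0.16 with Samul-tang, 1.33 ± 0.14 with Palmul-tang and 1.20 ± 0.14 with Sibjeondaebo-tang.

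If the full effects of Sagunja-tang and Samul-tang added up in Palmul-tang, its high minus low dose effect would equal their sum. By edgeR 48 genes deviated from the sum and 0 from the mean of the 2 effects (1560 and 695 at an unadjusted p under 0.05), with a median SE of 0.153 for the sum and 0.101 for the mean. The test had asked for fewer genes to deviate from the sum than from the mean, and this failed. Palmul-tang combines the herbs of both, so at equal mass of extract it need not hold the full dose of either. The test therefore cannot decide whether the effects add. It also crosses groups whose sample codes begin differently.

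A further hypothesis was that the changes at the low doses of Sagunja-tang and Samul-tang and those between Sibjeondaebo-tang and Palmul-tang were one pattern of transcripts moved in opposite directions. Their correlation across 11001 genes was 0.0473 (0.0522 with trends removed), while the test had asked for a correlation under -0.1, so the result across all of these genes was negative. Among the 613 genes lower with Sibjeondaebo-tang, however, 197 were called higher and 30 lower at low-dose Sagunja-tang, and 175 higher and 34 lower at low-dose Samul-tang. An opposite movement of that part of the genes therefore stays open.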
